A study of Homo sapiens with 12 samples.

How the data were processed

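RNA from MCF7 cells, an established human breast cancer cell line, was labelled with Cy3 and hybridized singly to 12 Agilent whole-genome arrays, in 4 groups of 3. The deposited Feature Extraction files gave, for each of 45015 spots per array, a background-subtracted and detrended signal as an intensity, together with the mean spot intensity, the local background and quality flags. Per the file headers the software was Agilent Feature Extraction 9.5.3.1, whereas the processing notes of the submitters name version 9.1. The deposited value table held log2 values that correlated with the log2 mean spot signal at r of at least 0.9965 across probes within each array and had the same median, 5.745, on every array. The table was therefore read as quantile-normalized without background subtraction and was used only as an alternative. Probes were placed by the files on genome build hg17.

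Of the 43376 non-control spots per array, those with a non-uniformity or population flag were set to missing, and spots of the same probe were averaged, which left 41000 distinct probes. Saturated spots would have been kept, but no array had any (0 spots). Probes were named by accession (23434), by current symbol (2317) or by an earlier symbol (1043), and 14206 kept the name given in the file only. No probe could be named CARM1 (0 probes). A probe was measured when it lay well above background on all 3 arrays of at least 1 group, which 25802 probes did. Each of the resulting 19349 genes was represented by its measured probe with the highest mean signal. The tested genes had 299 missing values.

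Signals were taken to log2 and each array's 75th percentile was subtracted, so that a level of 0 is that percentile. Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, on values read with the data.table package (version 1.17.8), and variances were moderated with a trend on the mean level. Contrasts were E2 against untreated, Dox+E2 against Dox, Dox against untreated, Dox+E2 against E2, the difference between the E2 effects (the interaction), and the average E2 and Dox effects. All tests were two-sided and p-values were adjusted by Benjamini and Hochberg over the genes of a contrast, with calls at an adjusted p under 0.05. Errors beside log2 differences are standard errors of that fit, and SDs are between the 3 arrays of a group. Where a group was above background on none of its arrays, the difference was given as a bound. The bound used the lowest signal well above background on those arrays, or the measured level where higher. A group above background on only some of its arrays kept its measured difference.

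The groups, contrasts, tests, 21 gene lists, measured-probe rule, named-gene rule and most alternatives were fixed before the data were examined. For each single contrast the named-gene rule took the 10 largest rises and the 10 largest falls with an adjusted p under 0.05 and no overlap between the groups, among genes with a symbol. Such non-overlap arises by chance for 10% of genes when 3 arrays are compared with 3. The rule also took up to 4 members of each list with the smallest adjusted p, and for the interaction the 10 smallest passing p-values.

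The lists covered estrogen-induced genes, estrogen-repressed genes, G1/S and DNA replication genes, G2/M genes, p53 target genes, interferon response genes, ATF4 and amino acid stress genes, endoplasmic reticulum chaperone genes, nuclear genes of oxidative phosphorylation, glycolysis and hypoxia genes, sterol and fatty acid synthesis genes, ribosome biogenesis genes and immediate early genes. They also covered protein arginine methyltransferases, estrogen receptor coregulators, luminal epithelial genes, basal and mesenchymal genes, immune cell genes, aryl hydrocarbon receptor genes and housekeeping control genes. The remaining list, cell cycle inhibitors and differentiation genes recalled from the study, was chosen by the study and is not independent evidence of its direction. Lists with at least 4 measured members were tested with camera in limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 21 lists of a contrast. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move on balance in a given direction and does not compare the list with other genes.

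The procedure was tested on simulated data made from the means and spreads of the genes on these arrays. Noise was drawn independently for each gene and array, without correlation between genes and without slide or day differences. Among 19349 genes, changes of 1.5-fold, 2-fold and 4-fold were recovered at 8.96%, 61.2% and 89.4% for Dox against untreated, and at 0%, 16.4% and 78.8% for the interaction. A simulated ratio of E2 responses of 0.7 was recovered as 0.694. Camera and fry each called the list raised in the simulation and 0 of the other 20 lists. These lists were random sets of uncorrelated genes, so the result does not bear on the preset correlation.

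Alternatives were quantile and median scaling, normexp background correction with an offset of 50, no filter on dim probes, a filter for probes above background on all arrays, keeping the outlier spots, the mean of the probes of a gene, limma without the variance trend, array weights, a replicate block, a slide block, the deposited value table, only the arrays of the groups compared, and leaving out each array in turn. Removal of each array's trend on probe GC content, slide as a random block and the emphasis on results without Dox replicate 1 were chosen after seeing the data.

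The number of arrays, 3 per group, limits the precision. The series describes its replicates as biological, but nothing states that they were separate cultures, so the p-values measure only the spread between these samples. The labels call the control group untreated while the series text describes it as vehicle-treated, and the Dox samples carry a 4 h treatment time although their titles place them before E2. The label untreated is used here. Replicate numbers did not pair the samples, since the deviations from the group means of only 3 of 18 pairs of arrays with the same number correlated above 0.1. The arrays lay on 4 slides read on 2 days. Slide 1 held the untreated arrays and Dox replicate 1, slide 2 the E2 arrays and Dox+E2 replicate 1, slide 3 Dox replicates 2 and 3, and slide 4 Dox+E2 replicates 2 and 3. Slides 1 and 3 were read on a different day from slides 2 and 4. The level of CARM1 was left out because no probe could be given that name, which leaves open whether 1 of the probes known only by the name in the file measures it.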

Results

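Gene expression was measured in 12 samples of an MCF7 clone that carries a doxycycline-inducible hairpin RNA against CARM1, an arginine methyltransferase known as a coactivator of the estrogen receptor. The 4 groups of 3 arrays were untreated cells, cells given 10 nM estradiol (E2) for 4 h, cells given 1 µg/ml doxycycline (Dox) for 5 days, and cells given Dox and then E2. The design asks how the response to estrogen differs when the hairpin is expressed. The 75th percentile of the array signal ran from 114.4 to 346.2 intensity units, and 56.55% to 66.85% of spots lay well above background. No probe could be named CARM1 (0 probes), so the depth of the knockdown is not known, and the design has no Dox control without the hairpin.

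Arrays with E2 parted from arrays without it along the first principal component, which held 57.2% of the variance. The arrays with E2 were also read on a different day from those without it. The E2 and Dox+E2 arrays had scores from 42 to 66, the untreated arrays from -68.1 to -53.2, and Dox replicates 2 and 3 scores of -48.1 and -54.9. Dox replicate 1 stood apart at -16 on this component and at 75.7 on the next component, where the other 11 arrays ran from -30.2 to 9.82. On that array the 30 estrogen-induced genes that rose with E2 in cells without Dox had a mean log2 level of 1.70, against -0.54 and -0.56 on the other Dox arrays.

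**Figure D1:**
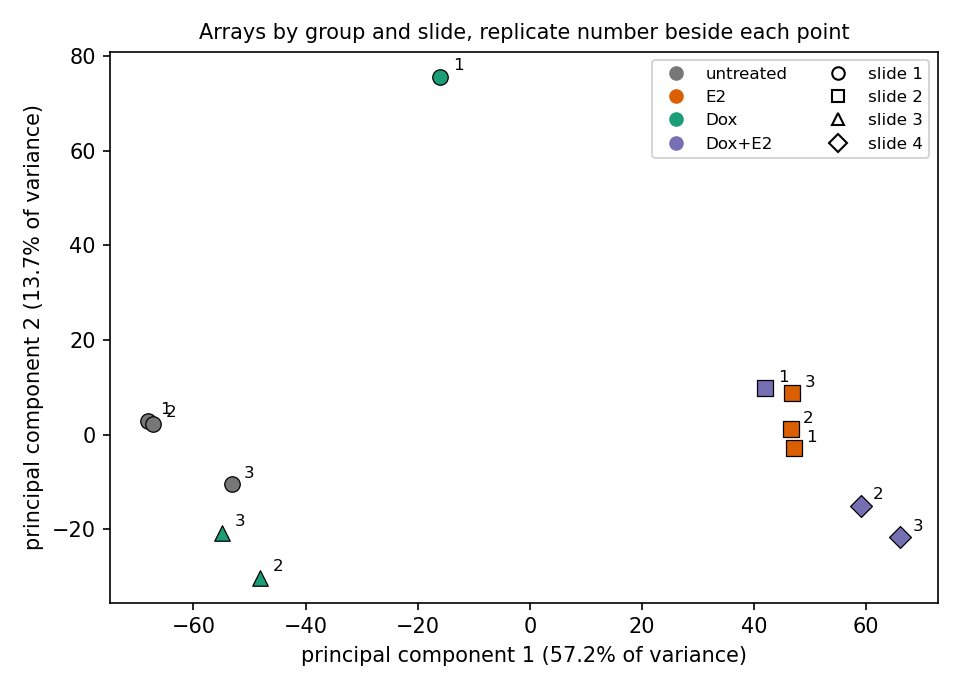
Principal component 1 (57.2% of variance, x axis) against principal component 2 (13.7% of variance, y axis) of the log2 levels, with a point per array, coloured by group, shaped by slide and numbered by replicate. Arrays with E2 lie at 42 or more on the x axis, and Dox replicate 1 lies alone at 75.7 on the y axis.

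**Figure D2:**
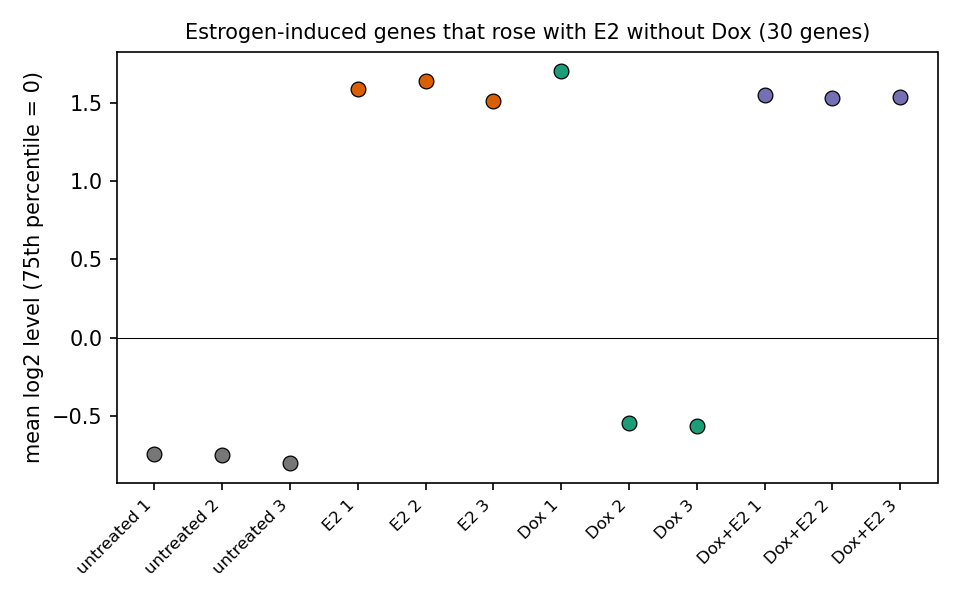
Mean log2 level (y axis, array 75th percentile = 0) of the 30 estrogen-induced genes that rose with E2 in cells without Dox, with a point per array in group order (x axis). Dox replicate 1 lies at 1.70, beside the 6 arrays with E2 at 1.51 to 1.64, and the other 5 arrays without E2 lie at -0.54 or lower.

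Comparing E2 with untreated cells gives the hormone response with the hairpin off, together with any difference between slides and scan days. FOS, a subunit of the AP-1 transcription factor, rose 43.9-fold, from a log2 level of -2.04 ± 0.33 to 3.41 ± 0.05 (SD, n = 3 and 3). GREB1, a known estrogen receptor target, rose 19.1-fold (log2 4.26 ± 1.09 SE, adjusted p = 0.00833, with a further probe at 2.56), and STC2, a secreted glycoprotein, 21.6-fold (4.44 ± 0.66, adjusted p = 0.000355). MAG, a glycoprotein of myelin, rose 45-fold (5.49 ± 0.53, adjusted p = 3.75e-05). HOPX, a homeodomain protein, fell by 4.30 on the log2 scale (SE 1.00, adjusted p = 0.00485), and LYPLA1, a protein thioesterase, fell by 3.12 (SE 0.18, adjusted p = 2.51e-06). For every gene in this paragraph the 3 arrays of E2 lay beyond the 3 untreated arrays, as the named-gene rule required.

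The FOS probe lies on chromosome 14 at 74817967 to 74818026 (hg17) and that of GREB1 on chromosome 2 at 11733278 to 11733337. The others lie as follows, that of STC2 on chromosome 5 at 172676973 to 172677032, that of MAG on chromosome 19 at 40496421 to 40496480 and that of LYPLA1 on chromosome 8 between 55126264 and 55127789. The other largest rises were RASGRP1 (log2 4.53 ± 0.56 SE), PPM1K (4.52 ± 0.86), and 4 genes not above background in untreated cells, which were at least 14.2-fold (SMTNL2), 11.1-fold (EGR3), 7.06-fold (MPPED2) and 16.2-fold (AMZ1) higher. Other large falls were ARHGEF37 (-3.34 ± 0.61), RBM7 (-2.91 ± 0.33), PTGER4 (-2.90 ± 0.63), PHOSPHO2 (-2.79 ± 0.30) and FAM171B (-2.78 ± 0.53, with further probes at -0.69 and -0.41). PWWP3B, PANK1 and DLSTP1, dim with E2, were at least 7.18-fold, 3.39-fold and 2.35-fold lower, with calls that were lost with normexp background correction, and EGR3 was not called in the deposited value table.

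Estrogen-induced genes rose as a group: 30 of 44 measured members rose, 1 fell and 13 were not called, or 34 rose and 1 fell when adjusted over the list alone. Their median log2 difference was 1.43 (camera adjusted p = 8.91e-06, and adjusted p = 0.801 with an estimated correlation). Examples are MYC, a transcription factor of growth genes (3.33 ± 0.50 SE, adjusted p = 0.000395, with a further probe at 0.96), and the retinoic acid receptor RARA (2.86 ± 0.42, adjusted p = 0.000339, with a further probe at 1.00). Ribosome biogenesis genes rose with them, 22 of 25 with 0 falls (24 and 0 adjusted over the list alone). Their median was 1.30 (camera adjusted p = 4.23e-06, and adjusted p = 0.774 with an estimated correlation), as for the nucleolar proteins NOP2 (2.34 ± 0.41) and NOP16 (1.97 ± 0.32). Of the immediate early genes 14 of 18 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 1.27 (camera adjusted p = 4.23e-06, and adjusted p = 0.305 with an estimated correlation). Among them were EGR1 (2.48 ± 0.15), JUN (2.41 ± 0.18) and the phosphatase DUSP1 (2.78 ± 0.22).

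The other lists were not called by camera. Estrogen-repressed genes had 1 rise and 4 falls in 15 (1 and 4 adjusted over the list alone), with falls of CCNG2 (-2.26 ± 0.48 SE) and TGFB3 (-1.79 ± 0.48), and camera gave an adjusted p of 0.277. G1/S and DNA replication genes had 4 rises and 8 falls in 30 (4 and 7; adjusted p = 0.24), with falls of the DNA repair enzyme UNG (-1.94 ± 0.18) and of TYMS (-0.88 ± 0.14). G2/M genes had 8 rises and 1 fall in 30 (7 and 1; adjusted p = 0.581), with KIF20A at 1.20 ± 0.22 and CDK1 at -0.79 ± 0.09. The 5 cell cycle inhibitors and differentiation genes recalled from the study, a list that is not independent evidence, had 0 rises and 2 falls (0 and 2; adjusted p = 0.408), with CDKN1B at -1.19 ± 0.22 and CDKN1A not called at -0.09. Nuclear genes of oxidative phosphorylation had 3 rises and 10 falls in 24 (4 and 10; adjusted p = 0.0665), with falls of NDUFB5 (-1.74 ± 0.13) and ATP5F1B (-1.55 ± 0.17).

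Stress and metabolic lists gave the following counts, with those adjusted over the list alone in parentheses. p53 target genes had 6 rises and 7 falls in 23 (7 and 8; camera adjusted p = 0.482), with CCNG1 at -1.61 and SESN1 at -1.23, and their median (0.03) and mean (-0.03) differ in sign. Interferon response genes had 9 rises and 1 fall in 21 (9 and 1; adjusted p = 0.277), with OAS1 at 1.74 and IFI27 at 1.71. ATF4 and amino acid stress genes had 9 and 4 in 24 (9 and 4; adjusted p = 0.662), with ATF3 at 1.09 and PCK2 at 0.55. Endoplasmic reticulum chaperone genes had 3 and 3 in 17 (2 and 3; adjusted p = 0.879), with DNAJB9 at -0.77. Glycolysis and hypoxia genes had 8 and 3 in 25 (8 and 5; adjusted p = 0.665), with PFKFB3 at 1.48 and BNIP3 at -1.26, and sterol and fatty acid synthesis genes 8 and 8 in 28 (10 and 11; adjusted p = 0.429), with IDI1 at -1.89 and SC5D at -1.22.

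Protein arginine methyltransferases had 2 rises and 2 falls in 8 (2 and 2 adjusted over the list alone; camera adjusted p = 0.658), with PRMT6 at 0.85 ± 0.14 SE and PRMT1 at -0.77 ± 0.18. Estrogen receptor coregulators had 5 and 2 in 17 (5 and 3; adjusted p = 0.939), with PELP1 at 1.15 ± 0.14 and the receptor gene ESR1 at -0.73 ± 0.16 (a further probe at -0.10). The median of this list (0.09) and its mean (-0.08) differ in sign. Luminal epithelial genes had 8 and 3 in 19 (8 and 5; adjusted p = 0.697), with KRT8 at 1.53 and AGR2 at -1.52. Basal and mesenchymal genes had 5 and 2 in 11 (5 and 2; adjusted p = 0.277), with SNAI1 at 1.98 and TP63 at -1.65. Immune cell genes had 1 and 0 in 5 (1 and 0; adjusted p = 0.882), the rise being CD79A (1.05), with a median of -0.07 and a mean of 0.28, and aryl hydrocarbon receptor genes had 2 and 3 in 7 (2 and 4; adjusted p = 0.482), with NQO1 at -1.17. Housekeeping control genes had 5 and 3 in 14 (6 and 3; adjusted p = 0.879), with TFRC at -1.16 and B2M at -1.05. The rise of GAPDH (0.41) was lost with quantile scaling, normexp, the value table and slide as a random block, and turned to -0.005 when the probe GC trend was removed.

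In all, limma called 8633 of 19349 genes, 5225 higher and 3408 lower with E2, of which 3852 and 2555 differed by at least 1.5-fold. Where a called gene had a further measured probe, 1861 of 2319 such probes (80.3%) differed in the same direction. The median of all genes was 0.118 in this contrast and 0.102 for E2 with Dox, so that small differences are relative to the scaling. The share of calls that were higher was 60.5%, but 48.5% with median scaling, 52.3% with quantile scaling, 51.1% in the deposited value table, 48.6% with the probe GC trend removed, 75.2% with normexp and 77.6% without the filter on dim probes. With slide as a random block 4795 genes were called. From the E2 and untreated arrays alone 11027 were called, and 10995 without Dox replicate 1, whose spread the main fit pools. No slide and no scan day held arrays with and without E2, so E2 and scan day cannot be told apart in any E2 contrast.

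Comparing Dox+E2 with Dox gives the same comparison with the hairpin on, again together with any difference between slides and scan days. STC2 rose 10-fold (log2 3.33 ± 0.66 SE, adjusted p = 0.00206, n = 3 and 3). For STC2 the fit without Dox replicate 1 gave 4.42 ± 0.20, beside 4.44 in cells without Dox. FOS rose by 1.91 ± 0.24 (adjusted p = 0.000109). KAZN, which encodes the cell junction protein kazrin, rose by 3.08 ± 0.36 (adjusted p = 7.79e-05, with a further probe at 3.23), and CD86, a costimulatory receptor, by 3.11 ± 0.52 (adjusted p = 0.000683). LYPLA1 fell by 2.97 (SE 0.18, adjusted p = 2.09e-06), RCHY1, a ubiquitin ligase, fell by 2.64 (SE 0.13, adjusted p = 2.09e-06), and PRDX3, a mitochondrial peroxiredoxin, fell by 2.51 (SE 0.18, adjusted p = 5.98e-06). For each of these genes all 3 arrays of Dox+E2 lay beyond all 3 of Dox, which the named-gene rule required for all but FOS.

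Further rises among the largest were ASAP1-IT1 (log2 3.58 ± 0.55 SE), SLC12A4 (3.36 ± 0.47), SND1-IT1 (3.35 ± 0.46), MPPED2 (3.23 ± 0.69), MAG (3.09 ± 0.53), SMTNL2 (3.02 ± 0.82) and LINC00597, at least 3.3-fold higher. Further falls were KDM6A (-3.54 ± 1.08), RBM7 (-3.39 ± 0.33), CIP2A (-2.88 ± 0.32), TMEM64 (-2.63 ± 0.23), PHOSPHO2 (-2.56 ± 0.30), and NEXMIF and EFHB, which were at least 2.86-fold and 4.19-fold lower, with further probes at -0.89 and -0.68. The calls of RBM7, CIP2A, NEXMIF and EFHB were lost with normexp. Leaving out Dox replicate 1 gave 4.37 for SMTNL2, 4.31 for MPPED2, 3.97 for MAG, 4.05 for SLC12A4, 4.19 for ASAP1-IT1 and 3.72 for CD86, each over 1.5 times the fold given. SMTNL2 lost its call without Dox replicate 3 (2.27, adjusted p = 0.0525), and KDM6A without Dox replicate 2 (-3.44, adjusted p = 0.0524) and without Dox replicate 3 (-3.29, adjusted p = 0.0648).

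With Dox present, 14 of the 44 estrogen-induced genes rose, 1 fell and 29 were not called (14 and 1 adjusted over the list alone). Their median was 0.58 (camera adjusted p = 0.0203, and adjusted p = 0.813 with an estimated correlation), but 1.12 without Dox replicate 1 (camera adjusted p = 4.63e-13), the array on which these genes were high. Examples are RARA at 2.04 ± 0.42 SE (a further probe at 0.58) and the potassium channel gene KCNK5 at 1.96 ± 0.39, which without Dox replicate 1 were at 2.73 and 2.60. Immediate early genes rose, 12 of 18 with 0 falls (12 and 0 adjusted over the list alone), with a median of 1.12 (camera adjusted p = 1.54e-05, and adjusted p = 0.204 with an estimated correlation). NR4A1 (1.73 ± 0.15, with a further probe at 0.73), ZFP36 (1.42 ± 0.14) and IER3 (1.19 ± 0.13) were among them. Nuclear genes of oxidative phosphorylation fell, 11 of 24 with 0 rises (12 and 0 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 1.54e-05, and adjusted p = 0.204 with an estimated correlation). The respiratory chain subunits NDUFB5 (-1.94 ± 0.13), NDUFS2 (-1.51 ± 0.13) and SDHB (-1.18 ± 0.12) fell. G1/S and DNA replication genes fell in 14 and rose in 2 of 30 cases (15 and 2 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.00131, and adjusted p = 0.505 with an estimated correlation), among them RFC4 (-1.13 ± 0.11) and PCNA (-0.78 ± 0.13). Ribosome biogenesis genes rose in 9 of 25 cases with 0 falls (12 and 0 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 0.0354, and adjusted p = 0.813 with an estimated correlation; 1.05 without Dox replicate 1), NOP2 at 1.83 ± 0.41 (2.49 without that array) being an example.

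The remaining lists were not called in Dox+E2 against Dox, and their rises and falls were as follows, with those adjusted over the list alone in parentheses. Estrogen-repressed genes had 2 and 0 in 15 (2 and 0), G2/M genes 5 and 3 in 30 (3 and 3), with CDK1 at -1.05 ± 0.09 SE, and the genes recalled from the study, again not independent evidence, 0 and 1 in 5 (0 and 1), with CDKN1B at -0.82 ± 0.22. Counts were 6 and 6 in 23 for p53 target genes (7 and 6), 5 and 0 in 21 for interferon response genes (5 and 0), 5 and 3 in 24 for ATF4 and amino acid stress genes (5 and 3) and 0 and 4 in 17 for endoplasmic reticulum chaperone genes (0 and 4). Glycolysis and hypoxia genes had 5 and 5 in 25 (5 and 5), sterol and fatty acid synthesis genes 7 and 11 in 28 (7 and 11), protein arginine methyltransferases 1 and 2 in 8 (1 and 2) and estrogen receptor coregulators 4 and 1 in 17 (4 and 1). PRMT1 was at -1.17 ± 0.18 and IDI1, of isoprenoid synthesis, at -1.57 ± 0.18. Counts were 5 and 3 in 19 for luminal epithelial genes (5 and 3), 5 and 1 in 11 for basal and mesenchymal genes (5 and 1), 0 and 0 in 5 for immune cell genes (0 and 0), 3 and 0 in 7 for aryl hydrocarbon receptor genes (3 and 0) and 2 and 4 in 14 for housekeeping control genes (2 and 4). Their camera adjusted p-values ran from 0.103 (sterol and fatty acid synthesis genes) to 0.984 (G2/M and p53 target genes). The median, mean and test direction differed in sign for G2/M genes (0.12, 0.01 and lower), p53 target genes (0.08, 0.11 and lower) and the recalled genes (0.06, -0.24 and lower).

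In this contrast limma called 7399 genes, 4152 higher and 3247 lower with E2, of which 3103 and 2332 differed by at least 1.5-fold. Of the calls 56.1% were higher, against 31.5% with median scaling, 51.5% with quantile scaling, 44.3% with the probe GC trend removed and 51.9% in the deposited value table. With slide as a random block 3192 genes were called, from the Dox and Dox+E2 arrays alone 4716, with array weights 11156 and without Dox replicate 1 9354. The calls of estrogen-induced and ribosome biogenesis genes were lost without Dox replicate 2 (camera adjusted p = 0.217 and 0.184), without Dox replicate 3 (0.168 and 0.169) and without Dox+E2 replicate 1 (0.0665 and 0.0701), and that of ribosome biogenesis genes also without Dox+E2 replicate 3 (0.0711) and with normexp (0.112).

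**Figure D3:**
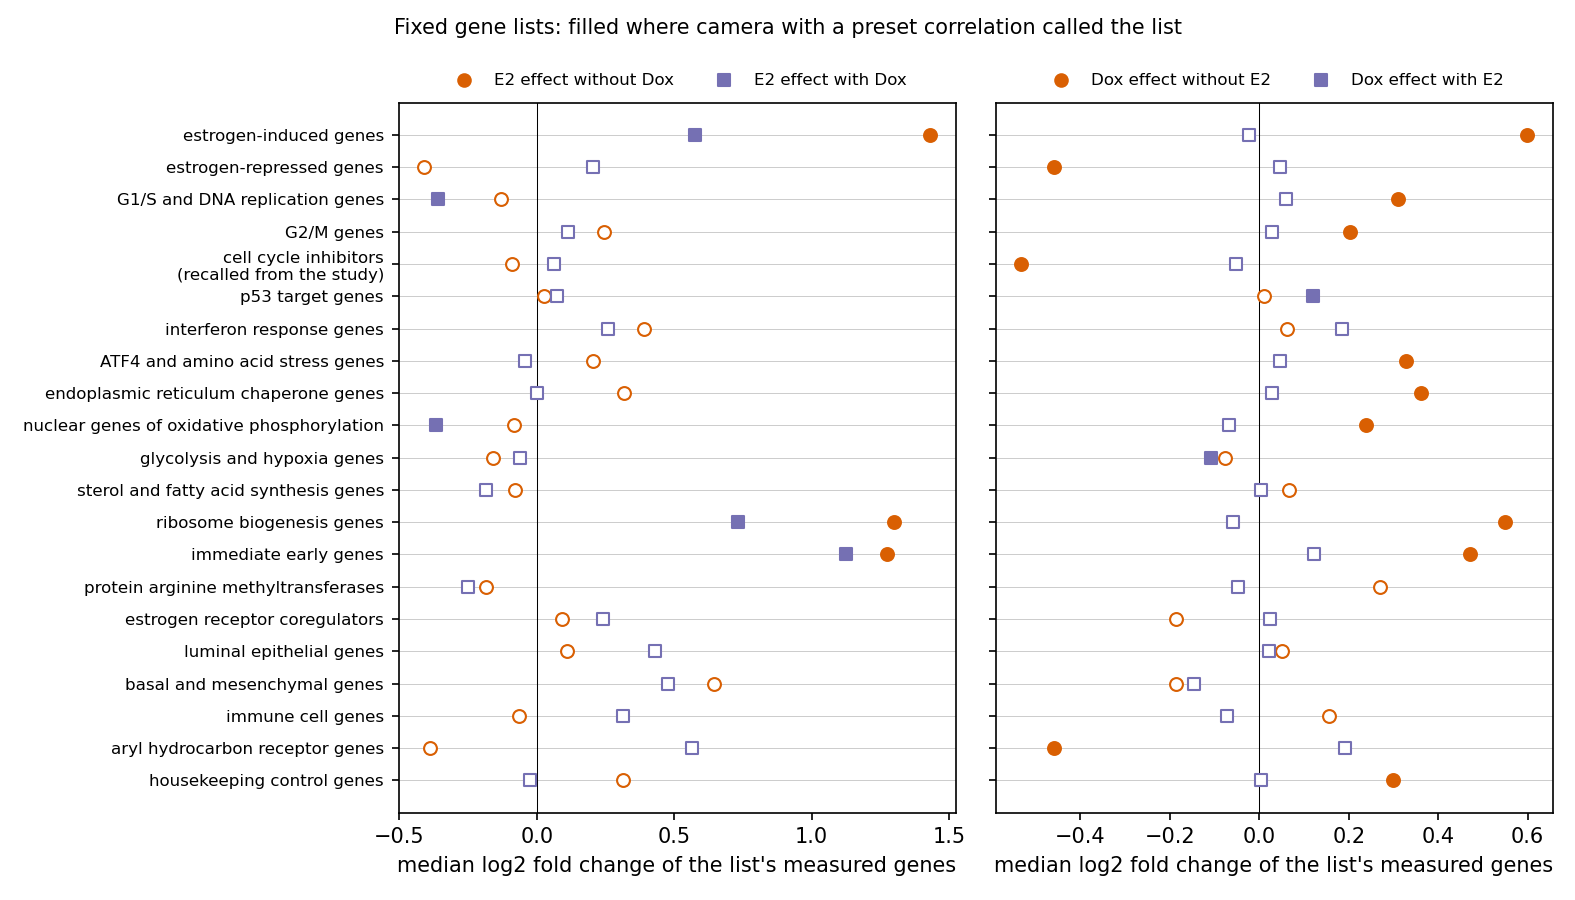
Median log2 difference (x axis) of the measured members of each of the 21 gene lists (y axis), for E2 without and with Dox (left) and for Dox without and with E2 (right), filled where camera with the preset correlation called the list. Estrogen-induced, ribosome biogenesis and immediate early genes have medians of 1.43, 1.30 and 1.27 with E2 alone and of 0.58, 0.73 and 1.12 with E2 and Dox, where the fit without Dox replicate 1, not drawn, gave 1.12, 1.05 and 1.30.

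Both E2 contrasts called FOS, STC2, MAG, MPPED2, SMTNL2, LYPLA1, RBM7 and PHOSPHO2 in the same direction. Of the genes called in both, 5404 differed in the same direction and 4 in opposite directions, where independent lists of these sizes would share 1690 in the same direction. Both contrasts also hold the same difference between scan days, so they are not independent. The overlap therefore does not tell hormone from scan day. Averaged over Dox, E2 raised 6610 genes and lowered 4459 (11069 in all), and with slide as a random block 4761 genes were called. The balance depended on such choices, with 4537 higher and 5943 lower for median scaling, 4893 and 5340 with the probe GC trend removed and 9136 and 3510 with normexp. Camera called 5 lists for this average, and 0 with an estimated correlation. Immediate early genes had a median of 1.18 with 15 rises and 0 falls in 18 (adjusted p = 0.366 with an estimated correlation), estrogen-induced genes 1.04 with 33 and 2 in 44 (0.822) and ribosome biogenesis genes 0.98 with 21 and 0 in 25 (0.822). Nuclear genes of oxidative phosphorylation had a median of -0.21 with 3 rises, 11 falls and 10 not called (0.618), and G1/S and DNA replication genes -0.19 with 4 rises, 14 falls and 12 not called (0.754).

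The size of the E2 response was compared over those 11069 genes. Their median signed difference was 0.690 without Dox and 0.631 with Dox, a ratio of 0.914. For the genes raised by E2 the ratio was 0.873, and for those lowered 0.979. Over the 39 fixed estrogen-induced genes with a higher average it was 0.503, with 37 smaller with Dox. Fry on the interaction called none of these differences in size. In the fit without Dox replicate 1, added after the data were seen, the fixed estrogen-induced genes gave a ratio of 0.794. Here 24 of 41 genes were smaller with Dox. Fry called this at 0.05 as a single unadjusted test, and camera did not call the list (median -0.02). The ratio over all responsive genes was 0.992 without Dox replicate 1, with 0.915 for the genes raised and 1.09 for those lowered. For the genes raised and lowered it was 0.73 and 1.16 with median scaling, 0.61 and 1.01 with normexp and 0.521 and 0.974 without the filter on dim probes.

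Comparing Dox with untreated cells gives the difference with doxycycline and the induced hairpin together, which the design cannot separate, in the absence of hormone. FOS rose 12.3-fold, from -2.04 ± 0.33 to 1.58 ± 0.31 (SD, n = 3 and 3; log2 difference 3.62 ± 0.24 SE, adjusted p = 2.62e-05), and EGR1, a zinc finger transcription factor induced early by growth signals, rose by 1.31 ± 0.15 (adjusted p = 0.00694). SLC48A1, a heme transporter, fell by 1.75 (SE 0.13, adjusted p = 7.32e-05), from 0.63 ± 0.22 to -1.12 ± 0.05. DSP, which encodes the desmosomal protein desmoplakin, fell by 0.89 (SE 0.13, adjusted p = 0.0238). Other calls were ZNF488 (2.06 ± 0.31), IFI27 (1.17 ± 0.18), RHBDL3 (1.10 ± 0.16), the Rho GTPase activating protein DLC1 (1.02 ± 0.16) and the matrix protein CCN1 (0.82 ± 0.12). All were higher on the 3 Dox arrays than on the 3 untreated arrays, as the named-gene rule required.

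In total 18 genes were called, 11 higher and 7 lower, with 4145 at an unadjusted p under 0.05. The SLC48A1 probe lies on chromosome 12 at 46461578 to 46461637 and the DSP probe on chromosome 6 at 7531581 to 7531640 (hg17). Beyond the genes with a symbol, and chosen after their values were seen, the probe LOC51057 was 3.15 ± 0.12 higher with Dox (adjusted p = 1.18e-07) and AB014766 fell by 3.49 (SE 0.33). Within slide 1, which holds Dox replicate 1 and the untreated arrays, FOS differed by 3.93, EGR1 by 1.62, SLC48A1 by -1.80 and DSP by -1.14, and with a slide block their adjusted p-values were 7.04e-07, 4.66e-05, 2.58e-05 and 0.000128. The other called genes differed there by 2.77 (ZNF488), 1.56 (IFI27), 1.19 (RHBDL3), 1.38 (DLC1) and 0.85 (CCN1), and the slide block called 6653 genes, which rest on Dox replicate 1 alone. FOS and SLC48A1 were called under every alternative tried, whereas EGR1 was lost without untreated replicate 1 (1.30, adjusted p = 0.0553) and without untreated replicate 3 (1.25, adjusted p = 0.0509), and the 6 other named genes were each lost under 9 to 19 alternatives. Without untreated replicate 1, 2 or 3, 5 genes were called each time, 9 without E2 replicate 1, 10 without Dox replicate 2, 8 without Dox replicate 3 and 741 without Dox replicate 1, which kept all 18.

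Across the lists, camera called 12 of 21 in Dox against untreated cells, but 0 with an estimated correlation, and fry called 8. Estrogen-induced genes had a median of 0.60 with only FOS called (1 rise and 0 falls in 44, also adjusted over the list alone; camera adjusted p = 0.000102, and adjusted p = 0.464 with an estimated correlation). Ribosome biogenesis genes had a median of 0.55 with 0 calls in 25, or 1 rise adjusted over the list alone, NHP2 at 0.55 ± 0.14 SE (camera adjusted p = 1.51e-05, and adjusted p = 0.41 with an estimated correlation). Estrogen-repressed genes had a median of -0.46 with 0 calls in 15, also adjusted over the list alone (camera adjusted p = 0.00673, and adjusted p = 0.41 with an estimated correlation). On slide 1 the medians of these lists were 1.91, 1.46 and -1.32. They were 0.05, 0.18 and -0.05 without Dox replicate 1, and none of the 3 was called (camera adjusted p = 0.973, 0.0684 and 0.25).

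Immediate early genes rose in 2 of 18 cases (FOS and EGR1), or 7 adjusted over the list alone, with 0 falls and a median of 0.47 (camera adjusted p = 0.000512, and adjusted p = 0.355 with an estimated correlation), and DUSP1 (1.30 ± 0.22 SE, adjusted p = 0.0626) and FOSB (1.67 ± 0.28, adjusted p = 0.0661) were not called over all genes. G1/S and DNA replication genes had 0 calls in 30, or 10 rises adjusted over the list alone, with a median of 0.31 (adjusted p = 0.000114, and adjusted p = 0.355 with an estimated correlation), E2F1 being at 0.74 ± 0.13 and CDC45 at 0.49 ± 0.12. Aryl hydrocarbon receptor genes had 0 calls in 7, or 4 falls adjusted over the list alone, with a median of -0.46 (adjusted p = 0.00233, and adjusted p = 0.355 with an estimated correlation), UGT1A6 at -1.19 ± 0.21 and NQO1, a quinone reductase, at -0.91 ± 0.22. Slide 1 gave medians of 0.60, 0.17 and -0.96 for these lists, and without Dox replicate 1 they were 0.21, 0.34 and -0.25, all still called. The call of G1/S and DNA replication genes was lost with normexp (0.21, camera adjusted p = 0.111) and with a slide block (0.17, 0.264).

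Of the other lists called in this contrast, nuclear genes of oxidative phosphorylation had a median of 0.24 with 0 calls in 24 (0 adjusted over the list alone; camera adjusted p = 0.00146, and adjusted p = 0.355 with an estimated correlation). Endoplasmic reticulum chaperone genes had 0.36 and 0 calls in 17 (3 rises adjusted over the list alone; 0.00238 and 0.355), ATF4 and amino acid stress genes 0.33 and 0 in 24 (2 rises; 0.0163 and 0.409), and G2/M genes 0.20 and 0 in 30 (0; 0.0254 and 0.529). The genes recalled from the study, not independent evidence, had -0.53 and 0 calls in 5 (0; 0.00748 and 0.355). The called median of housekeeping control genes, 0.30 with 0 calls in 14 (1 rise; 0.0153 and 0.355), was -0.02 with quantile scaling and -0.01 in the value table. Their call was lost in both (camera adjusted p = 0.953 and 0.844), with normexp (0.17, camera adjusted p = 0.352) and with a slide block (0.06). The oxidative phosphorylation call was lost with quantile scaling (0.04, camera adjusted p = 0.31), in the value table (0.08, 0.204) and with normexp (0.17, 0.495). Also lost were the ATF4 and G2/M calls with quantile scaling (0.0783 and 0.196), the ATF4 and endoplasmic reticulum chaperone calls with normexp (0.254 and 0.21) and the G2/M call in the value table (0.24) and without untreated replicate 3 (0.206). Slide 1 gave medians of 0.24, 0.55, 0.45, 0.54, -0.94 and 0.06 for these 6 lists in that order. Leaving out Dox replicate 1, the calls of endoplasmic reticulum chaperone, ATF4, G2/M and recalled genes were lost (camera adjusted p = 0.156, 0.209, 0.649 and 0.0702), those of the oxidative phosphorylation and housekeeping genes were kept in that fit, and interferon response genes were called in addition (median 0.19, adjusted p = 0.0196).

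The 9 lists not called by camera in Dox against untreated cells had few called members. Interferon response genes had 1 rise (IFI27) and 0 falls in 21 (3 and 0 adjusted over the list alone), and the remaining 8 had 0 rises and 0 falls over all genes. Adjusted over the list alone, sterol and fatty acid synthesis genes had 4 rises in 28 and estrogen receptor coregulators 1 fall in 17 (DDX17 at -0.47 ± 0.11 SE). The p53 target, glycolysis and hypoxia, luminal epithelial, basal and mesenchymal and immune cell genes and the protein arginine methyltransferases had 0. Their camera adjusted p-values ran from 0.214 (protein arginine methyltransferases) to 0.72 (immune cell genes), and PRMT7, at 0.33 ± 0.12, had the smallest adjusted p among the methyltransferases (0.158). The test was toward lower levels although median and mean were above 0 for p53 target genes (0.01 and 0.004) and immune cell genes (0.16 and 0.01).

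Comparing Dox+E2 with E2 gives the difference with doxycycline and the hairpin together in hormone-treated cells. SLC48A1 fell by 1.26 (SE 0.13, adjusted p = 0.00136), from 0.76 ± 0.15 to -0.50 ± 0.05 (SD, n = 3 and 3). RPRM, which encodes the cell cycle inhibitor reprimo, fell by 1.13 (SE 0.13, adjusted p = 0.00427), and DSP fell by 1.01 (SE 0.13, adjusted p = 0.00897). ACTG2, a smooth muscle actin, rose by 0.93 ± 0.14 (adjusted p = 0.0421) and TARP, a transcript of the T cell receptor gamma locus, by 0.84 ± 0.12 (adjusted p = 0.0237). All 3 Dox+E2 arrays lay beyond all 3 E2 arrays for each of these genes, as the named-gene rule required.

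In total 11 genes were called, 3 higher and 8 lower, with 1198 at an unadjusted p under 0.05. LOC51057 and AB014766, chosen after their values were seen, differed by 2.93 ± 0.12 and -4.29 ± 0.33 here. Within slide 2, which holds the E2 arrays and Dox+E2 replicate 1, SLC48A1 differed by -1.21, RPRM by -1.10, DSP by -0.94, ACTG2 by 0.76 and TARP by 0.95. These differences rest on Dox+E2 replicate 1 alone, as do the adjusted p-values from the slide block (0.0347, 0.0175, 0.0458, 0.167 and 0.0237). SLC48A1 was called under every alternative tried. RPRM was lost without E2 replicate 2 (-1.09, adjusted p = 0.0524), DSP under 6 alternatives, TARP under 13 and ACTG2 under 18. Without E2 replicate 2, 6 genes were called, and without Dox replicate 1, 81, which kept all 11.

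Camera called 2 lists in Dox+E2 against E2, 0 with an estimated correlation, and fry called 1. For p53 target genes the median was 0.12 with 0 calls in 23 (0 adjusted over the list alone; camera adjusted p = 0.0413, and adjusted p = 0.136 with an estimated correlation), SPATA18 being at 0.59 ± 0.17 SE and MDM2 at 0.43 ± 0.20. For glycolysis and hypoxia genes the median was -0.11 with 0 calls in 25 (0; adjusted p = 0.0445, and adjusted p = 0.136 with an estimated correlation), MXI1 being at -0.51 ± 0.17. Both calls were lost without E2 replicate 1 (camera adjusted p = 0.0894 and 0.118), without E2 replicate 3 (0.141 and 0.141) and without Dox+E2 replicate 1 (0.289 and 0.125), and that of glycolysis and hypoxia genes also without Dox+E2 replicate 2 (0.0961). A replicate block lost both as well (camera adjusted p = 0.0509 for each). The glycolysis and hypoxia call was also lost with quantile scaling (-0.10, camera adjusted p = 0.0649) and with a slide block (-0.14). Slide 2 gave medians of 0.16 and -0.14 for these lists.

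None of the 21 lists had a member called over all genes here (0 rises and 0 falls in each). Adjusted over the list alone, there was 1 rise among immediate early genes and 1 among ATF4 and amino acid stress genes, both being ATF3 (0.80 ± 0.19 SE), and 1 among basal and mesenchymal genes (TP63 at 0.67 ± 0.18). Estrogen-induced genes had 1 rise, the retinoic acid hydroxylase gene CYP26B1 (1.44 ± 0.37), and 1 fall, TFF3, which encodes a trefoil factor (-0.71 ± 0.17). There was 1 fall among luminal epithelial genes, again TFF3, and 1 among the genes recalled from the study (MAZ at -0.73 ± 0.19), and the remaining lists had 0. The median of estrogen-induced genes was -0.02 (camera adjusted p = 0.741), and the other lists not called had camera adjusted p-values from 0.161 (interferon response genes) to 0.839 (protein arginine methyltransferases). Medians just above 0 went with means below 0 for sterol and fatty acid synthesis (0.004 and -0.014), housekeeping control (0.003 and -0.013), luminal epithelial (0.02 and -0.03) and estrogen receptor coregulator genes (0.02 and -0.01).

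**Figure D4:**
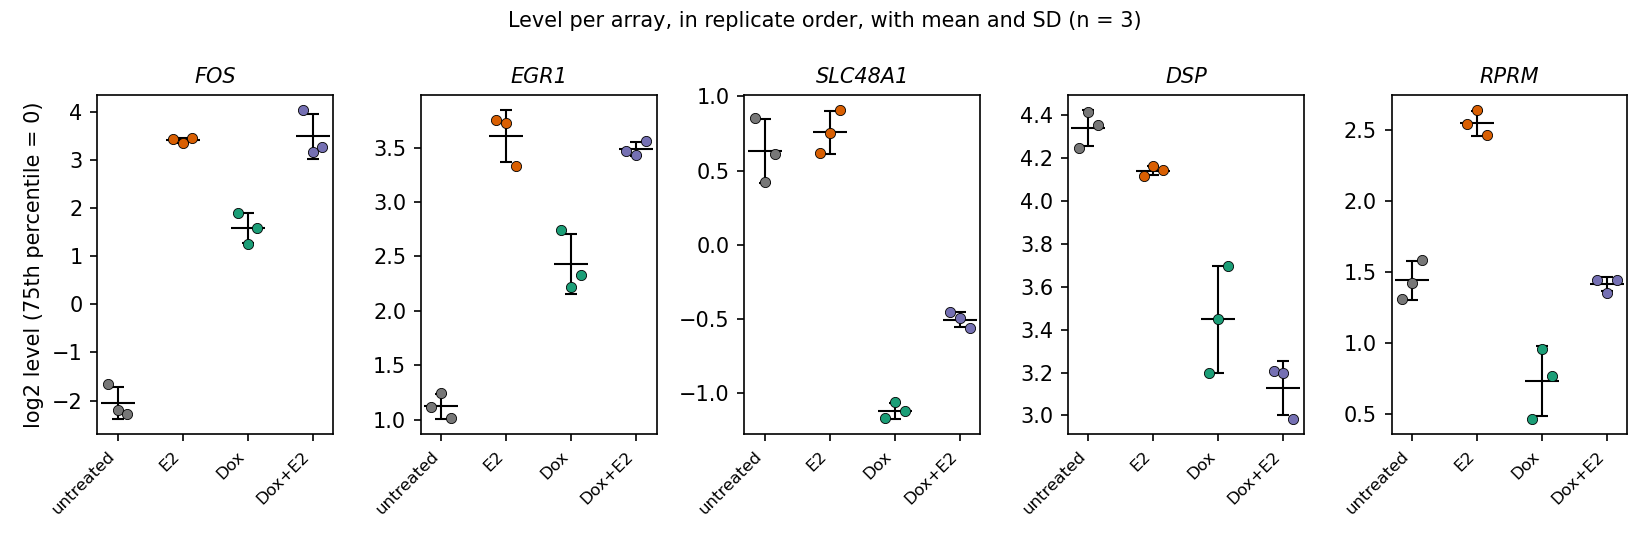
Log2 level (y axis, array 75th percentile = 0) of FOS, EGR1, SLC48A1, DSP and RPRM in the 4 groups (x axis), with a point per array in replicate order, the group mean as a long bar and the SD (n = 3) as the error bar. FOS lies at -2.04 in untreated cells, 1.58 with Dox, 3.41 with E2 and 3.49 with both.

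The interaction asks whether the E2 effect differs with and without Dox. FOS was the only gene called (1 of 19349): its E2 effect was smaller by 3.55 with Dox (log2 difference -3.55 ± 0.33 SE, adjusted p = 0.0033), as FOS reached 3.41 ± 0.05 with E2 and 3.49 ± 0.47 with Dox+E2 from different levels without hormone (SD, n = 3 in each group). It was called under every alternative tried, with values from -3.82 to -2.69. Within slides 1 and 2 the difference was -3.32, which rests on 1 array in each Dox arm, among them Dox replicate 1. An unadjusted p under 0.05 was reached by 2062 genes, and without Dox replicate 1, 16 genes were called. On simulated data without slide or day differences the interaction test recovered 78.8% of 4-fold changes and 16.4% of 2-fold changes.

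Camera called 10 of 21 lists for the interaction, 0 with an estimated correlation, and fry called 3. Among them, estrogen-induced genes had a median of -0.64 with only FOS called (1 fall in 44, also adjusted over the list alone; camera adjusted p = 0.000126, and adjusted p = 0.488 with an estimated correlation), but -0.02 without Dox replicate 1 (camera adjusted p = 0.832). Estrogen-repressed genes had 0.66 (0.00617 and 0.48), and 0.16 without that array (0.143). Ribosome biogenesis genes had -0.59 (2.01e-05 and 0.48), nuclear genes of oxidative phosphorylation -0.30 (0.000126 and 0.212) and aryl hydrocarbon receptor genes 0.73 (0.000355 and 0.212), of which 4 of 7 rose adjusted over the list alone. These last 3 lists were called without Dox replicate 1 too, at -0.23, -0.32 and 0.60. Immediate early genes had -0.21 (0.0184 and 0.48; 1 fall, or 3 adjusted over the list alone), which was 0.07 without Dox replicate 1 (0.419). G1/S and DNA replication genes (-0.19; 0.0184 and 0.48), endoplasmic reticulum chaperone genes (-0.30; 0.0184 and 0.48), p53 target genes (0.11; 0.0365 and 0.212) and housekeeping control genes (-0.29; 0.0184 and 0.458) had 0 called members. The endoplasmic reticulum chaperone call was lost without Dox replicate 1 (-0.22, camera adjusted p = 0.419), and that of G1/S and DNA replication genes with quantile scaling (-0.009, 0.647), normexp, a slide block, the value table and in 4 of 12 fits without a single array. With quantile scaling the oxidative phosphorylation (-0.10, 0.129), housekeeping (-0.05, 0.767), immediate early (-0.17, 0.0723) and endoplasmic reticulum chaperone calls (-0.15, 0.197) were lost too. Normexp also lost the immediate early, housekeeping and chaperone calls (camera adjusted p = 0.0628, 0.245 and 0.292). So did the value table (0.287, 0.611 and 0.25). The immediate early call was also lost without untreated replicate 3, E2 replicate 2, Dox+E2 replicate 2 or Dox+E2 replicate 3. The housekeeping call was lost with a slide block and without Dox replicate 2, and the chaperone call without untreated replicate 2 or Dox+E2 replicate 2. The p53 call was lost with median scaling (-0.005, camera adjusted p = 0.0725), with a slide block (0.05, 0.599) and in 7 of 12 fits without a single array. The 11 lists not called had 0 members called over all genes and camera adjusted p-values from 0.147 to 0.859, with 1 rise among basal and mesenchymal genes adjusted over the list alone. Signs differed between median, mean and test for interferon response genes (0.08, -0.01 and lower), basal and mesenchymal genes (0.003, -0.02 and higher) and immune cell genes (-0.25, -0.06 and higher). With a slide block, which rests on 1 array in each Dox arm, camera called 10 lists.

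Averaged over E2, Dox lowered SLC48A1 by a log2 difference of -1.50 ± 0.09 SE, DSP by -0.95 ± 0.09, RPRM by -0.92 ± 0.09 and the glycosyltransferase GALNT2 by -0.91 ± 0.12, and raised ACTG2 by 0.77 ± 0.10, LY6D by 1.06 ± 0.15 and TPM1, a tropomyosin, by 0.52 ± 0.08. In all 40 genes were called, 21 higher and 19 lower, with 3016 at an unadjusted p under 0.05. Without Dox replicate 1, 833 were called, which kept all 40, and without a single other array between 19 (E2 replicate 1) and 69 (Dox+E2 replicate 1). The 2 Dox contrasts shared 8 called genes in the same direction, where independent lists of these sizes would share 0.0046. Camera called 7 lists for this average, 0 with an estimated correlation, and fry called 3. Immediate early genes had a median of 0.37 (camera adjusted p = 0.000262, and adjusted p = 0.417 with an estimated correlation), with 2 rises in 18 (8 adjusted over the list alone), FOS and FOSB, and G1/S and DNA replication genes 0.17 (0.000262 and 0.479), with 1 rise in 30 (8), E2F1 at 0.55 ± 0.09. Estrogen-induced genes had 0.30 (0.00539 and 0.541), ribosome biogenesis genes 0.24 (0.00312 and 0.541), endoplasmic reticulum chaperone genes 0.19 (0.0119 and 0.479), ATF4 and amino acid stress genes 0.17 (0.0374 and 0.479) and the recalled genes -0.35 (0.0132 and 0.479). Only the calls of immediate early (0.25, camera adjusted p = 0.011) and G1/S and DNA replication genes (0.20, 9.48e-05) remained without Dox replicate 1. The others were lost, namely estrogen-induced (0.03, 0.927, with the test toward lower levels), ribosome biogenesis (0.08, 0.824), endoplasmic reticulum chaperone (0.16, 0.176), ATF4 (0.14, 0.216) and recalled genes (-0.12, 0.173), and interferon response genes were gained (0.16, 0.011). The call of G1/S and DNA replication genes was lost with a slide block (median 0.05). With a slide block, which rests on 1 array in each Dox arm, 3692 genes and 9 lists were called.

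Over the 6610 genes raised by E2 on average, the median average Dox effect was 0.09, higher for 4438 and lower for 2172 (camera p = 4.79e-05, p = 0.147 with an estimated correlation and p = 0.0584 with fry, all in limma). Over the 4459 genes lowered by E2 it was -0.04, higher for 1860 and lower for 2599 (camera p = 0.000336, p = 0.275 with an estimated correlation and p = 0.476 with fry). With Dox replicate 1 left out the medians were 0.06 and 0.01, and camera called neither. The genes were chosen on the same arrays. The average E2 and Dox effects are uncorrelated in a balanced design whose arrays share the same spread. Dox replicate 1, with an array weight of 0.0957, departed from that spread, and the fit without it is not balanced. The medians and these p-values are therefore not taken as independent of the E2 contrasts.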

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

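The tests of scan day, of probe GC content and of Dox replicate 1 were chosen after the results they concern had been seen, while the tests on Dox replicates 2 and 3 and the splits of the samples were set before. The E2 effect on FOS differed between cells with and without Dox by -3.55 on the log2 scale in a test of the difference itself.

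The E2 contrasts called 8633 and 7399 genes, and their list calls were all lost with an estimated correlation (0 of 21 lists in each). That correlation was estimated with Dox replicate 1 included, which deviates from its group on estrogen-induced genes, and was not estimated without it. A trend on probe GC content between arrays is argued against as the whole source, since 77% of the calls in E2 against untreated cells (6645 of 8633) were kept in the same direction after each array's trend was removed. A difference between scan days or slides stays open for any part of these calls, because 0 of the scan days held arrays with and without E2. The hormone and the scan day cannot be told apart, and only arrays of both kinds on a shared slide and day would separate them.

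Dox replicate 1, labelled as without hormone, carried estrogen-induced genes at a mean log2 level of 1.70, beside 1.51 to 1.64 on the arrays with E2. An exchange of labels with an array of this set is argued against, since 0 of the 6 arrays with E2 lay at the level of the other arrays without it. RNA of the E2 groups mixed in would keep its level at or below theirs, and 46.7% of the 30 called genes (14) lay above all 6 arrays with E2. Dox replicate 1 was read on another slide and day than those arrays, so these levels cannot decide on mixed-in RNA. An effect of the slide is argued against by a gap of 2.44 to the highest untreated array beside a range of 0.061 among these. Mixed-in RNA, a single wrong label, a sample from outside this set or exposure of that culture to hormone could each account for the pattern. They stay open with no biological explanation tested, although SLC48A1 (-1.17, against -1.06 and -1.12 on the other Dox arrays) had the level of the Dox group. Over all genes called in E2 against untreated cells, Dox replicate 1 lay 0.195 (median) toward E2 from the other Dox arrays, with 65% of genes in that direction. Over a different set, the genes responsive to E2 on average, the median response without Dox was 0.69. Both sets also hold any difference between scan days, which the Dox arrays, all read on the same day, cannot show. These values therefore do not measure how far that array responded to hormone.

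Between Dox and untreated cells 741 genes were called without Dox replicate 1, and the 2 remaining Dox arrays share slide 3. Over the 685 of these genes that were also among the genes tested on all 12 arrays, signed by that difference, Dox+E2 replicates 2 and 3 on slide 4 lay at 0.237 and 0.260 above the mean of the E2 arrays, and Dox+E2 replicate 1, on slide 2 with the E2 arrays, at -0.0225, inside the range of the E2 arrays (-0.13 to 0.071). Handling shared by slides 3 and 4 may therefore be part of these calls, a reading that rests on 1 array. A difference of slide 3 from slide 1 alone cannot be told apart from Dox by the same value (-0.0225), because the Dox+E2 arrays neither all lay above that range nor all inside it. An effect of doxycycline or of the hairpin, the difference named by the design, also stays open. SLC48A1, DSP and RPRM kept their direction within slides 1 and 2, where each Dox arm is 1 array.

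Other splits of the samples were fitted in the same way. For each comparison of 3 arrays with 3, 1 of 10 splits, the real one, gave as many calls (8633, 7399, 18 and 11), the highest other split gave 0, and 10 splits are too few for a share under 0.05. In the E2 comparisons every other split mixed arrays with and without E2 within a group. That widened the pooled spread, so the 0 calls there do not bear on chance. For the interaction 14 of 100 drawn splits gave at least the real count of 1, so chance is not excluded for the count, and the highest other split gave 135, several times the real count, which points to a structure of the samples. For the average E2 effect 1 of 100 splits, the real one, gave as many calls as 11069. The highest other split gave 5213 and placed Dox replicate 1 on the side of E2 replicates 1 to 3 and Dox+E2 replicates 1 and 3. The real split also follows scan day, so its higher count does not tell hormone from scan day. For the average Dox effect 2 of 100 splits, the real one among them, gave at least the real 40. The highest other split gave 135, above the real count, so chance is not excluded for this count. That split also points to a structure of the samples.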

How the results depend on the processing

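The random slide block, the removal of the probe GC trend and the weight given to Dox replicate 1 were chosen after the data were seen. Each value below replaces the count given in the report, and the cause was not tested unless stated. The E2 effect without Dox gave 15833 calls with no filter on dim probes and 4795 with slide as a random block, the E2 effect with Dox 11156 with array weights, 3192 with slide as a random block and 4716 with only the arrays of the groups compared, and the average E2 effect 18802 with no filter and 4761 with slide as a random block. The Dox effect without E2 gave 4 with normexp, 2671 with array weights, 5 with a replicate block, 6653 with a slide block, 11 in the value table and 5 with only the arrays of the groups compared. The numbers of the replicates did not pair the samples, so the block on them is no paired test. The Dox effect with E2 gave 3 with normexp, 6 with probes above background on all arrays (fewer genes tested), 18 without the variance trend, 1018 with array weights and 17 with only the arrays of the groups compared. The interaction gave 567 with array weights and 3969 with a slide block. The average Dox effect gave 76 with quantile scaling, 13 with normexp, 2415 with array weights and 3692 with a slide block. Array weights gave Dox replicate 1 a weight of 0.0957 and the others 0.561 to 2.97, and the counts with weights were higher than those without that array.

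Leaving out each array in turn gave 6161 to 10995 calls for the E2 effect without Dox, 5521 to 9354 with Dox, 5 to 741 for the Dox effect without E2, 6 to 81 with E2, 1 to 16 for the interaction, 9880 to 12464 for the average E2 effect and 19 to 833 for the average Dox effect, each highest count being that without Dox replicate 1. A group left with 2 arrays was fitted with the spread pooled over all groups. The ratio of E2 responses ran from 0.855 to 0.992. Over the fixed estrogen-induced genes it was 0.503, which fry did not call, and 0.794 without Dox replicate 1, which fry called, a fit added after the data were seen. The Dox effect on genes raised by E2 ran from 0.058 to 0.14 and was not called without Dox replicate 1, and that on genes lowered ran from -0.063 to 0.006, with the sign reversed without Dox replicate 1. The number of list calls over all contrasts, 44, ran from 33 to 45, and was 0 with the estimated correlation.

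Among lists, the test direction of G2/M genes in the Dox effect without E2 was reversed with normexp (median 0.113) and without Dox replicate 1 (0.038, range 0.038 to 0.284), and that of estrogen-induced genes in the average Dox effect without Dox replicate 1 (0.034, range 0.034 to 0.467). Among named genes, normexp reversed PANK1 (0.008), DLSTP1 (0.15), NCOA2 (0.309, and 0.159 with Dox), CD14 (0.545) and CD8A (0.595) in the E2 contrasts, all near background, and removal of the GC trend reversed GAPDH (-0.005). Of the other comparisons of named genes with their alternatives, 11154 kept direction and side of the threshold, 263 lost the call, 210 gained it and 38 values that were never called changed sign. For lists the numbers were 2774, 165, 90 and 132, and for the counts and summary values 265 kept their size or call. The E2 contrasts, the ratio and the Dox effect on E2-responsive genes could not be fitted with a fixed slide block, the level of CARM1 gave no value under any alternative, and the contrasts over all groups have no version with fewer groups. Genes dim in a group are limited by signal over background, as 56.55% to 66.85% of spots were well above it.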

Other observations

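The genes in this part were named after their values were seen. Except for the probes known only by the name in the file, their values come from the fit without Dox replicate 1, whose emphasis was chosen after the data were seen. In that fit CA12, a carbonic anhydrase and known estrogen receptor target, rose with E2 by 3.01 ± 0.08 without Dox and 3.48 ± 0.09 with Dox (log2, SE). The chemokine gene CXCL12 rose by 3.24 ± 0.10 and 2.38 ± 0.12, and the transcription factor gene FOXC1 by 3.19 ± 0.09 and 3.37 ± 0.10. GREB1 rose by 4.26 ± 0.16 and 4.19 ± 0.18 and MYC by 3.33 ± 0.12 and 2.83 ± 0.14. TNFRSF11B, which encodes osteoprotegerin, had -2.58 ± 0.10 and -2.23 ± 0.11, and DDIT4L, a stress-responsive regulator of growth signalling, had -2.61 ± 0.12 and -2.59 ± 0.13. Of these genes none was called for the interaction in that fit, where MAG (-1.53 ± 0.23, adjusted p = 0.0483 in limma) and FOS (-3.39 ± 0.32, adjusted p = 0.00598) were among the 16 called.

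Without Dox replicate 1, Dox raised FOSB by 1.90 ± 0.27 and the neuropeptide gene GAL by 1.08 ± 0.11 in cells without E2, and lowered AKR1B10, an aldo-keto reductase (-2.01 ± 0.26), S100A8, a calcium-binding protein (-1.95 ± 0.26), and UGT1A6 (-0.90 ± 0.12). In cells with E2 it raised ABCG2, a drug efflux transporter, by 0.75 ± 0.09, ATF3 by 0.80 ± 0.13 and the amino acid transporter SLC7A5 by 0.66 ± 0.10, and lowered TMPRSS4 (-0.89 ± 0.10), IFITM1 (-0.83 ± 0.10), GFRA1 (-0.69 ± 0.10) and SERPINA3 (-1.07 ± 0.16). For these genes the 2 Dox arrays lie on a different slide from the untreated arrays, and 2 of the 3 Dox+E2 arrays on a different slide from the E2 arrays. Probes known only by the name in the file differed with Dox in both arms, among them LOC51057 (3.15 and 2.93, and 3.20 and 2.94 within slides 1 and 2), AB014766 (-3.49 and -4.29), AF222023 (-3.25 and -4.25) and LOC57400 (-1.87 and -2.87).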
